A study of Mus musculus with 6 samples.

How the data were processed

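RNA-seq libraries from the tibialis anterior of C57BL/6 mice aged 8 weeks, 3 labelled wild type and 3 labelled Mettl21e knockout, were compared. The values were deposited as FPKM per gene, 1 table per library, and per the submitters' processing notes TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse build mm10 were used. The role of each tool, the annotation release, strand assignment and any filtering of reads are not given in the sources used here. Each table held 41025 genes, of which 40452 had a symbol and 573 did not. Of these, 17892 to 18977 were above 0 in a library, and mitochondrial genes held 15.2% to 19.8% of the fragments. Groups and replicate numbers came from the sample titles. Positions, exons and transcripts were taken from a GENCODE annotation of the same mm10 assembly. Since strand assignment is not known, values of genes that overlap another gene on the other strand are uncertain. Overlaps were looked up for only part of the named genes, and among those this also holds for Vcp, Myl2, Myh2, Myh7, Tnnc1, Fbxo32 and Gm17720. Mettl21c is uncertain for an overlap with Gm15838 on its own strand.

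FPKM values are not counts, so the test fixed for FPKM was used and the count tests written for the case of raw counts were not run. The low values were examined for depth. For all 23559 genes above 0 in at least 1 library (100%), 1 whole gene length between 20 and 110000 bases made the values whole fragments in all 6 libraries, within a tolerance of 0.002 of a fragment. The lengths found equalled the exon union of the annotation for 14.5% of genes. The library totals recovered were 10752204, 10856669 and 8842349 fragments for libraries 1, 2 and 3 labelled wild type and 9708838, 10435095 and 8476591 for those labelled knockout, and the recovered gene fragments made up 99.7% of each total. From them, 1 fragment on a gene of 1 kb was worth 0.0921 to 0.118 FPKM, and exact Poisson intervals (95%) and a floor of 3 fragments were computed for Mettl21e. These cover counting error only.

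Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and no further scaling, over the 11383 genes with a mean of at least 1 FPKM. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Log2 differences are labelled knockout minus labelled wild type on the log2(FPKM + 1) scale, which understates the change of low genes. Mettl21e was also compared by an exact permutation test. Before the data were examined, 29 gene lists were fixed, covering the METTL21 family, protein breakdown, fibre types, metabolism, growth, stress, other cell types and the surroundings of the locus. The 28 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list moves 1 way without comparing it with other genes. Adjustment was over the 28 lists. A list score is the mean, over its members, of the deviation of log2(FPKM + 1) from the average over the 6 libraries.

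Named genes followed a rule fixed before the data were examined. It takes Mettl21e and the tested members of its family list, then up to 10 genes each way among those past the test with non-overlapping groups, or, where fewer than 10 qualify, the 10 genes with the smallest unadjusted p. From each list it takes members past the test, otherwise up to 2 members with the highest mean. No gene qualified under the test, and genes named outside the rule are said to be chosen after their values were seen. Some values of single genes that the rule or an overlap would name are not reported here.

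The alternatives fixed beforehand were subtraction of each library's median, quantile normalization, pseudocounts of 0.1 and 0.01, no filter on low values, a mean of at least 5 FPKM, the replicate number as a block, no mean-variance trend, library weights, and leaving out each library in turn. limma voom on the recovered fragments was added after seeing the data. The share of 50-base words that transcripts of a gene share with those of other genes was computed for Mettl21e and the 10 leading genes. No pair of libraries agreed within sampling noise in a chi-square test over genes with at least 20 shared fragments, so none was taken for a second copy of another. That test cannot show that the libraries came from separate mice. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

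The test was checked on simulated libraries with the spread of these data (11286 genes) and with noise drawn independently for each gene and library. It called 24 of 50 genes changed 1.5-fold, 85 of 100 changed 2-fold and 47 of 50 changed 4-fold, all in the right direction, along with 14 unchanged genes. These changes were simulated together, so the shares do not give the chance of finding a single changed gene. With no change simulated it called 2 genes. In a second simulation (11295 genes), camera with either correlation and fry called 5 of 5 lists of 25 genes shifted by -0.5. Camera with the preset correlation called 0 of 5 unshifted lists. The genes of these simulated lists varied independently, so the simulation cannot show how the preset correlation behaves for lists whose members move together. In the real libraries the estimated correlation was 0.22 for the slow fibre list and 0.86 for the fibroblast list. It was 0.05 for the heat shock list and -0.02 for the clock list, the latter below the preset 0.01. With the estimated correlation the unadjusted camera p of these 2 lists still rose, from 1.2e-07 to 0.0195 and from 0.00265 to 0.0309. A higher correlation thus cannot account for the lost call of the clock list.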

Results

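RNA was sequenced from the tibialis anterior, a hindlimb muscle made mostly of fast-contracting fibres, of C57BL/6 mice aged 8 weeks. Of the 6 libraries, 3 were labelled wild type and 3 were labelled Mettl21e knockout. Mettl21e encodes a muscle-enriched protein methyltransferase of the METTL21 family, which has been linked to proteasome activity and to the size of fast type IIb fibres. The comparison asks which transcripts differ in level between muscle with and without the gene. Each library gave FPKM values (fragment counts scaled by gene length and library total) for 41025 genes, and between 8476591 and 10856669 fragments stood behind a library. At that depth 1 fragment on a gene of 1 kb was worth 0.0921 to 0.118 FPKM. The replicates are described as biological, without a statement that each came from a mouse of its own, so the p-values measure the spread between these libraries.

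Mettl21e transcripts were not lower in the libraries labelled knockout. The gene (ENSMUSG00000046828) lies on the minus strand of chromosome 1 from 44204070 to 44218961 in mm10, is protein coding and has 8 annotated exons. It was at 1.64, 1.45 and 1.88 FPKM in the libraries labelled knockout (mean 1.66 ± 0.217, SD, n = 3) and at 2.46, 0.309 and 1.23 FPKM in those labelled wild type (mean 1.33 ± 1.08, SD, n = 3). These values correspond to 38, 36 and 38 recovered fragments in the libraries labelled knockout and to 63, 8 and 26 in those labelled wild type, where 3 fragments would have been worth at most 0.148 FPKM. The lowest of the 6, library 2 labelled wild type, has a 95% exact Poisson interval of 3.45 to 15.8 fragments, which covers counting error only. The log2 difference was 0.29 (SE 0.31, limma adjusted p = 0.988), and an exact two-sided permutation test of the FPKM gave p = 0.7, where 3 against 3 libraries allow no p below 0.1. Leaving out library 2 labelled wild type turned the difference to -0.07, and leaving out library 1 labelled wild type raised it to 0.63. The values are 1 per gene, so the loss of single exons was not analysed here, and a non-coding gene, Gm15833, overlaps Mettl21e on the other strand. The level of the targeted transcript thus does not tell the labels apart. Every direction below is therefore a direction between libraries labelled knockout and libraries labelled wild type.

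**Figure D1:**
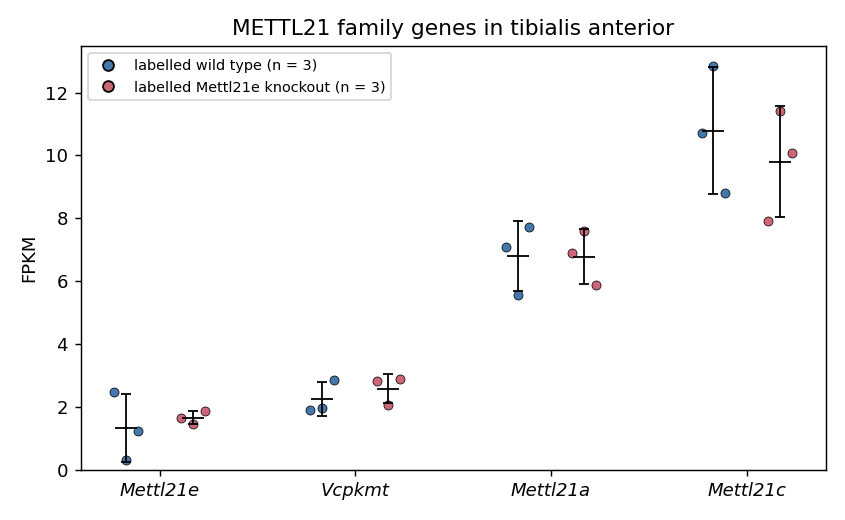
FPKM of Mettl21e, Vcpkmt, Mettl21a and Mettl21c (y axis, linear) in the 3 libraries labelled wild type and the 3 labelled knockout, with points for single libraries and bars for mean and SD. Mettl21e lies between 1.45 and 1.88 FPKM in the libraries labelled knockout and between 0.309 and 2.46 FPKM in those labelled wild type, and the groups overlap for all 4 genes.

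The relatives and reported substrates of the METTL21 enzymes showed no difference past the test. Of the 18 tested members of this list, 8 were higher and 10 lower in the libraries labelled knockout (camera adjusted p = 0.477), and 0 passed the test over all genes. Mettl21c, the neighbour of Mettl21e on chromosome 1, was at 10.8 ± 2.02 FPKM in libraries labelled wild type and 9.80 ± 1.78 FPKM in those labelled knockout (SD, n = 3 each). Mettl21a, which methylates Hsp70 proteins, was at 6.80 ± 1.11 and 6.78 ± 0.870 FPKM, and Vcpkmt, which methylates the ATPase encoded by Vcp, at 2.25 ± 0.536 and 2.58 ± 0.456 FPKM. Among the substrates, Hspa8 was at 694 ± 75.3 FPKM in libraries labelled wild type and 611 ± 43.4 FPKM in those labelled knockout, and Vcp at 319 ± 8.59 and 309 ± 25.3 FPKM. The chaperone Hspa5 was at 132 ± 6.39 and 112 ± 6.81 FPKM (log2 difference -0.24). In the same order, Mettl22 was at 95.3 ± 1.22 and 88.7 ± 0.239 FPKM, Mettl23 at 56.8 ± 8.38 and 57.7 ± 7.13 FPKM, Mettl18 at 2.62 ± 1.32 and 2.13 ± 0.618 FPKM and Eef2kmt at 3.94 ± 0.710 and 4.70 ± 1.21 FPKM. The Vcp cofactors Nploc4, Ufd1, Nsfl1c, Ubxn1, Faf1 and Aspscr1 differed by log2 values between -0.08 and 0.07. Without library 1 labelled wild type the direction of the list turned upward (adjusted p = 0.795). Camkmt and Eef1akmt3 were below the filter of a mean of 1 FPKM, and the inducible Hspa1a is described with the heat shock genes.

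Across the transcriptome, 0 of 11383 tested genes passed limma's test at a Benjamini-Hochberg adjusted p of 0.05, so 0 genes were called higher, 0 lower and 0 changed at least 2-fold. The smallest adjusted p was 0.290. At an unadjusted p under 0.05 there were 523 genes, 146 higher and 377 lower in the libraries labelled knockout, where 569 would be expected by chance. That count was 1357 without library 1 labelled wild type, 341 without library 3 labelled wild type and 343 without library 2 labelled knockout. limma voom on the recovered fragments, added after the data were examined, also called 0 genes, with 468 at an unadjusted p under 0.05. The groups did not overlap for 1079 genes, 9.48% of those tested, where chance gives 10%. On simulated libraries with the spread of these data, the same test found 85% of genes changed 2-fold. It found 48% of those changed 1.5-fold and 94% of those changed 4-fold. The simulated noise was independent for each gene, so these shares do not allow for structure shared by many genes of a library. The changed genes (50, 100 and 50) were simulated together, and many changed genes ease the Benjamini-Hochberg threshold. The shares are thus not the chance of finding a single changed gene here. In the real libraries 41 tested genes were at least 2-fold apart on the log2(FPKM + 1) scale, and 0 passed. Leaving out 1 library called 1 gene without library 1 labelled wild type (Igha, log2 difference -2.19, adjusted p = 0.0321) and 1 without library 3 labelled knockout (Gm2830, -1.70, adjusted p = 0.0103). Without library 3 labelled wild type, 3 genes were called: Myh7 (-2.78), Tnnc1 (-2.15) and Gm17720 (1.52), each with an adjusted p of 0.0228. These 5 genes were chosen after their values were seen, and leaving out any of the other 3 libraries called 0 genes.

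The 10 genes with the smallest unadjusted p all missed the adjusted test, and 7 of them were lower and 3 higher in the libraries labelled knockout. In each of the 10, the 3 libraries of one label lay outside the range of the other 3. Clu, the gene of the extracellular chaperone clusterin (chromosome 14, 65968483 to 65981547, plus strand), was at 63.4 ± 4.65 FPKM in libraries labelled wild type and 36.8 ± 2.77 FPKM in those labelled knockout (log2 difference -0.77, SE 0.09, adjusted p = 0.290). Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962, minus strand), was at 5.98 ± 1.01 and 1.92 ± 0.616 FPKM (log2 difference -1.27, adjusted p = 0.611), and Gm8425 overlaps it on the other strand, so its value is uncertain. Tnfrsf12a, the gene of the TWEAK receptor (chromosome 17, 23675445 to 23677468, minus strand), was at 27.7 ± 8.25 and 10.6 ± 2.58 FPKM (log2 difference -1.29). Gpx1, encoding a glutathione peroxidase (chromosome 9, 108338903 to 108340343, plus strand), was at 48.4 ± 2.36 and 33.6 ± 2.05 FPKM (log2 difference -0.51). Hspb8, a small heat shock protein gene (chromosome 5, 116408491 to 116422864, minus strand), was at 261 ± 7.25 and 201 ± 8.26 FPKM (log2 difference -0.38). The ferritin light chain gene Ftl1 (chromosome 7, 45457944 to 45459884, minus strand) was at 192 ± 8.41 and 146 ± 8.79 FPKM (log2 difference -0.40), but 58.4% of its 50-base words also occur in transcripts of other genes, so its level is uncertain. The same holds for Gm37758, an unclassified single-exon locus (chromosome 9, 33160062 to 33160690, minus strand), with 83.8% of words shared and 2.01 ± 0.614 against 0.566 ± 0.160 FPKM.

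Of the 3 leading genes that were higher, Rbm3, a cold-inducible RNA-binding protein gene (chromosome X, 8138975 to 8145880, minus strand), was at 30.8 ± 3.29 FPKM in libraries labelled wild type and 49.1 ± 5.15 FPKM in those labelled knockout (log2 difference 0.66), and Rbm3os overlaps it on the other strand, so its value is uncertain as well. Prom1, the gene of the membrane protein prominin 1 (chromosome 5, 43993620 to 44102032, minus strand), was at 1.42 ± 0.140 and 3.35 ± 0.492 FPKM (log2 difference 0.84), and the annotation has Gm42716 overlapping it on the same strand, so its value is uncertain. Gm11967, annotated as an antisense RNA, was at 2.45 ± 0.573 and 5.92 ± 1.48 FPKM (log2 difference 0.99). Whether fragments were assigned by strand is not given in the sources used here, so the value of Gm11967 is uncertain. Adjusted p lay between 0.659 and 0.893 for Gpx1, Prom1, Rbm3, Tnfrsf12a, Hspb8 and Gm11967 and was 0.988 for Ftl1 and Gm37758. All values are mean ± SD with n = 3 per label.

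**Figure D2:**
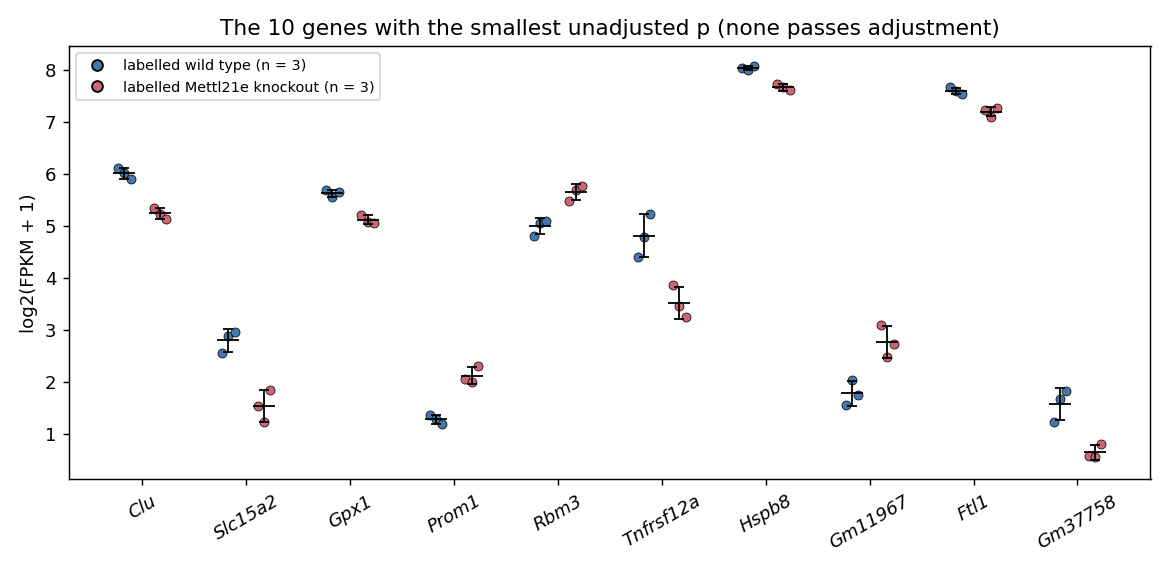
log2(FPKM + 1) of the 10 genes with the smallest unadjusted p (x axis) in the 3 libraries labelled wild type and the 3 labelled knockout, with points for single libraries and bars for mean and SD. The groups do not overlap for any of the 10 genes, such as Clu at 63.4 against 36.8 FPKM, while the smallest adjusted p is 0.290.

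Genes of slow and oxidative fibres were mostly lower in the libraries labelled knockout, and their list had the smallest p of the 28 in camera with a preset correlation. Of the 26 tested members, 23 were lower and 3 higher, with a median log2 difference of -0.49, and 13 had an unadjusted p under 0.05, all 13 of them lower. At that correlation of 0.01 the list passed (adjusted p = 2.8e-08) in a test that compares a list with all other tested genes. It missed it with an estimated correlation (adjusted p = 0.508) and missed fry (adjusted p = 0.459). Over all genes 0 members passed, and adjusted over the list alone 1 passed, Myl2, the slow myosin regulatory light chain, named after its values were seen, at 78.9 ± 24.8 FPKM in libraries labelled wild type and 31.9 ± 11.2 FPKM in those labelled knockout (log2 difference -1.29). The most abundant members were Mb, the oxygen-binding myoglobin, at 6546 ± 158 and 5701 ± 410 FPKM, and Mybpc1, slow myosin-binding protein C, at 1734 ± 194 and 1744 ± 284 FPKM. The stretch-responsive genes Csrp3 and Ankrd2 were at 518 ± 358 against 123 ± 85.4 FPKM and at 419 ± 252 against 113 ± 90.7 FPKM. Myh2, the myosin of oxidative type IIa fibres, was at 1285 ± 356 against 752 ± 395 FPKM. These 3 genes were named after their values were seen, and library 1 labelled wild type (105, 141 and 926 FPKM) lay inside the range of the libraries labelled knockout for each. Libraries 2 and 3 labelled wild type lay above that range, with library 3 at 695, 487 and 1290.4 FPKM.

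The type I genes within this list varied among the libraries labelled wild type, and library 3 lay inside the range of the libraries labelled knockout for 2 of 4 of them. Myh7, the type I myosin heavy chain, was at 7.23, 14.3 and 0.876 FPKM in libraries 1, 2 and 3 labelled wild type and at 0.549, 0.650 and 0.714 FPKM in libraries 1, 2 and 3 labelled knockout. Tnnt1, Tnnc1 and Tnni1, the slow troponins, were at 24.5, 23.4 and 11.7 FPKM in library 1 and at 30.7, 28.7 and 15.001 FPKM in library 2 labelled wild type. In library 3 labelled wild type they were at 6.24, 3.28 and 2.35 FPKM, and their means in libraries labelled knockout were 8.65 ± 3.03, 5.14 ± 1.26 and 2.67 ± 1.27 FPKM (SD, n = 3). For Tnnc1, library 3 labelled wild type lay below the range of the libraries labelled knockout (3.93 to 6.44 FPKM), and for Myh7 above it. These 4 genes were also chosen after their values were seen. The mean deviation of the whole list from its average over the 6 libraries was 0.23, 0.68 and 0.04 log2 units in libraries 1, 2 and 3 labelled wild type and -0.25, -0.13 and -0.57 in those labelled knockout.

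Fast-glycolytic fibre genes stood slightly higher, with 20 of 28 members higher and 8 lower in the libraries labelled knockout and a median log2 difference of 0.06. The list passed camera with the preset correlation (adjusted p = 0.0314) and missed it with an estimated correlation (adjusted p = 0.757). Its call was lost without library 2 labelled wild type (adjusted p = 0.343), without library 3 labelled wild type (0.373), without library 1 labelled knockout (0.186), and under quantile normalization (0.174), a mean FPKM of at least 5 (0.0536) and a fit with no mean-variance trend (0.0568). Tnnt3, fast troponin T, was at 17739 ± 1202 FPKM in libraries labelled wild type and 18661 ± 1425 FPKM in those labelled knockout, and Mylpf, the fast regulatory light chain, at 16323 ± 1453 and 14930 ± 397 FPKM. The score of this list in library 1 labelled wild type was 0.08, above every library labelled knockout (-0.01 to 0.06).

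**Figure D3:**
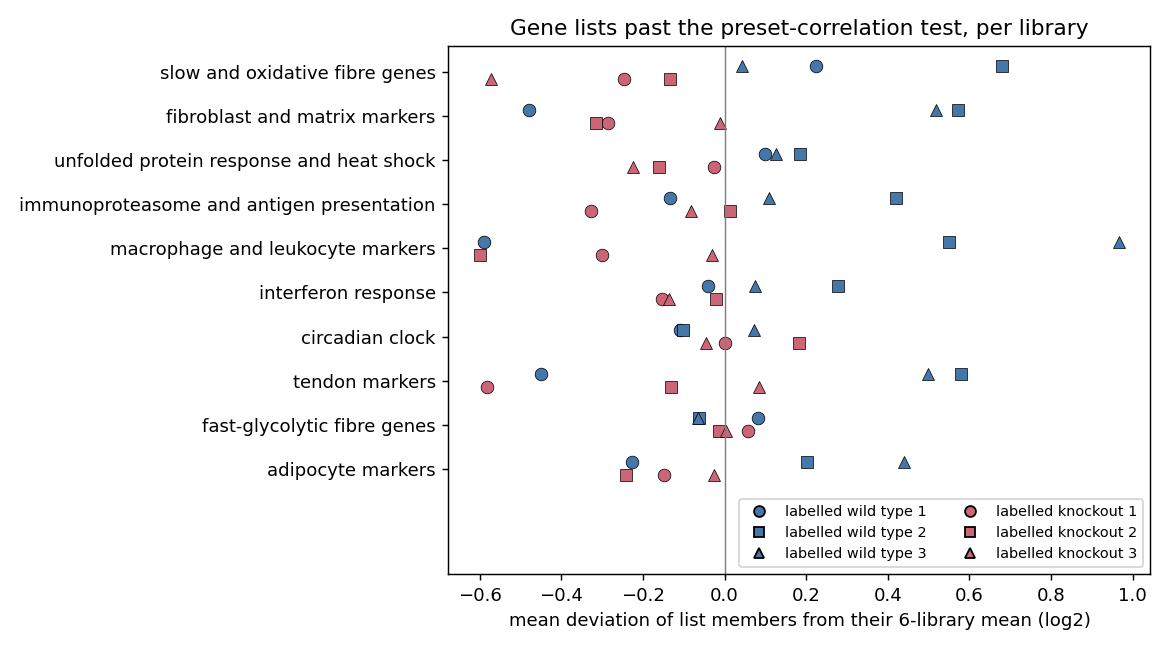
Mean deviation of the members of each of the 10 lists past camera with a preset correlation from their average over the 6 libraries (x axis, log2 units of FPKM + 1), with 1 symbol per library. For the slow and oxidative list the libraries labelled wild type lie at 0.04 to 0.68 and those labelled knockout at -0.57 to -0.13. For the fibroblast and matrix list library 1 labelled wild type lies at -0.48, below all 3 libraries labelled knockout.

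Heat shock and unfolded protein response genes were lower in the libraries labelled knockout for 24 of 30 members, with 6 higher, a median log2 difference of -0.19 and 9 members with an unadjusted p under 0.05, all 9 lower. The list passed camera with the preset correlation (adjusted p = 1.1e-06) and missed it with an estimated correlation (adjusted p = 0.433). Over all genes 0 members passed, and adjusted over the list alone 1 passed, Hspb8, at the values given above. The most abundant members were small heat shock protein genes: Cryab was at 1062 ± 268 FPKM in libraries labelled wild type and 640 ± 201 FPKM in those labelled knockout, and Hspb7 at 404 ± 175 and 212 ± 113 FPKM. The inducible Hsp70 gene Hspa1a was at 2.51 ± 0.263 and 1.38 ± 0.474 FPKM. Hsp90aa1, named after its values were seen, was at 51.2 FPKM in library 2 labelled wild type and at 2.26 to 3.72 FPKM in the other 5 libraries. Leaving out that library kept the list past the preset-correlation test (adjusted p = 8.9e-08).

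Markers of cells other than muscle fibres were lower in 4 lists past camera with the preset correlation, as was the antigen presentation list. Fibroblast and matrix markers were lower for all 24 members (median log2 difference -0.38, adjusted p = 7.4e-07 with the preset and 0.715 with an estimated correlation), with Gsn, which encodes gelsolin, at 349 ± 128 against 285 ± 31.8 FPKM and Sparc, a collagen-binding matrix protein gene, at 165 ± 39.7 against 128 ± 16.996 FPKM. Adjusted over the list alone 1 of them passed, Thy1, at 7.01 ± 1.44 against 3.81 ± 0.611 FPKM. Macrophage and leukocyte markers were lower for all 12 members (median -0.53, adjusted p = 1.0e-04 with the preset and 0.715 with an estimated correlation), with the antigen presentation genes Cd74 at 26.7 ± 13.0 against 16.5 ± 1.87 FPKM and H2-Ab1 at 27.2 ± 11.9 against 13.8 ± 1.47 FPKM. The leukocyte list holds S100a8 and S100a9, at 70.8 and 67.1 FPKM in library 3 labelled wild type. Elsewhere they were at most at 6.95 and 7.09 FPKM. Without that library the list still passed camera with the preset correlation (adjusted p = 0.0124). Immunoproteasome and antigen presentation genes were lower for all 15 members (median -0.31, adjusted p = 8.9e-05 with the preset and 0.715 with an estimated correlation), with H2-D1 at 148 ± 26.6 against 121 ± 11.8 FPKM and B2m at 137 ± 25.6 against 104 ± 15.7 FPKM. Tendon markers were lower for all 7 members (median -0.39, adjusted p = 0.0259 with the preset and 0.715 with an estimated correlation), with Thbs4 at 47.1 ± 20.9 against 33.5 ± 4.55 FPKM and Fmod at 17.8 ± 10.97 against 11.3 ± 6.12 FPKM. Adipocyte markers were lower for 11 of 12 members (median -0.23, adjusted p = 0.0314 with the preset and 0.715 with an estimated correlation), with the abundant carbonic anhydrase gene Car3, which muscle fibres also express, at 4117 ± 578 against 3698 ± 109 FPKM and Plin4 at 38.8 ± 13.4 against 47.3 ± 12.4 FPKM. Adjusted over the list alone 1 adipocyte marker passed, Cfd, at 24.96 ± 10.2 against 10.7 ± 2.24 FPKM. Thy1, Cfd, S100a8 and S100a9 were named after their values were seen.

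Interferon response genes were lower for 17 of 20 members (median -0.21, adjusted p = 0.00481 with the preset and 0.715 with an estimated correlation), with Bst2 at 14.7 ± 3.24 against 11.4 ± 4.39 FPKM and Irf1 at 8.79 ± 1.53 against 9.04 ± 1.13 FPKM. The libraries labelled wild type did not act as a block: the fibroblast list scored -0.48, 0.57 and 0.52 log2 units in libraries 1, 2 and 3 labelled wild type and -0.28, -0.32 and -0.01 in those labelled knockout. The tendon, leukocyte and adipocyte lists likewise scored -0.45, -0.59 and -0.23 in library 1 labelled wild type, against 0.58, 0.55 and 0.20 in library 2 and 0.50, 0.97 and 0.44 in library 3. The preset-correlation call was lost for the interferon list without library 2 labelled wild type (adjusted p = 0.235), without library 1 labelled knockout (0.0950) and with a mean FPKM of at least 5 (0.149). It was lost for the antigen presentation list without library 2 labelled wild type (0.0777) or library 1 labelled knockout (0.0800). For tendon markers it was lost without library 2 (0.415) or 3 (0.238) labelled wild type or library 1 labelled knockout (0.519). For adipocyte markers it was lost without library 2 (0.0780) or 3 (0.291) labelled wild type, without library 1 (0.139) or 2 (0.0537) labelled knockout, with a mean FPKM of at least 5 (0.317) and with voom (0.0535).

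**Figure D4:**
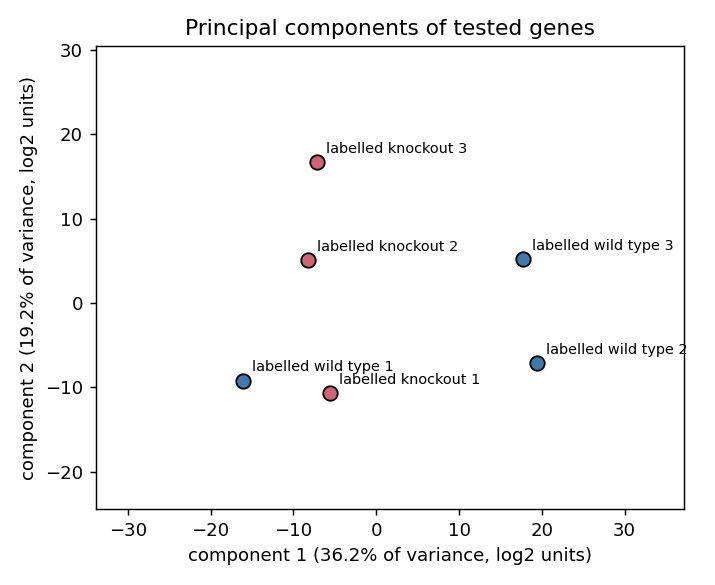
First and second principal components of log2(FPKM + 1) over the 11383 tested genes, with 1 point per library coloured by label. Library 1 labelled wild type lies at -16.1 on component 1 (36.2% of variance), on the side of the libraries labelled knockout (-8.29 to -5.58) and apart from libraries 2 and 3 labelled wild type (19.4 and 17.8).

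Library 1 labelled wild type was nearer to each library labelled knockout (SD of log2 differences over tested genes 0.281 to 0.308) than to libraries 2 and 3 labelled wild type (0.376 and 0.373). No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 7.64 to 26.4 over the 15 pairs.

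Genes of protein breakdown showed no group difference past the test. In the 26S proteasome list 17 of 46 members were higher and 29 lower in the libraries labelled knockout (median log2 difference -0.04, camera adjusted p = 0.489). The proteasome ATPase gene Psmc3 was at 222 ± 3.62 FPKM in libraries labelled wild type and 219 ± 4.91 FPKM in those labelled knockout, and the regulatory subunit gene Psmd2 at 198 ± 11.6 and 211 ± 4.84 FPKM. The direction of the proteasome list turned upward without library 1 labelled wild type (0.356) and with library weights (0.715). In the atrophy list 15 of 31 members were higher and 16 lower (adjusted p = 0.456), and its median of -0.01 went against the upward direction of camera. Its most abundant members were Ubb at 451 ± 27.8 and 440 ± 28.0 FPKM and Nedd4 at 192 ± 10.2 and 196 ± 5.87 FPKM. The muscle ubiquitin ligase genes Trim63 and Fbxo32, named after their values were seen, were at 114 ± 24.5 against 116 ± 5.21 FPKM and at 28.2 ± 5.08 against 34.6 ± 4.45 FPKM. The atrophy list passed the preset-correlation test without library 1 labelled wild type (adjusted p = 0.0307) and without library 3 labelled knockout (0.0298), and turned downward without library 2 labelled knockout (0.957). Autophagy and lysosome genes were higher for 12 and lower for 14 of 26 members (adjusted p = 0.579), with Ctsd at 501 ± 43.3 and 450 ± 3.999 FPKM and Sqstm1 at 425 ± 21.9 and 393 ± 41.4 FPKM.

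Growth, innervation and regeneration genes likewise missed the test as groups. Growth signalling genes were higher for 10 and lower for 18 of 28 members (camera adjusted p = 0.765), with Akt2 at 187 ± 13.4 FPKM in libraries labelled wild type and 181 ± 9.07 FPKM in those labelled knockout and Akt1 at 69.8 ± 9.65 and 60.7 ± 4.77 FPKM. The growth list turned upward without library 3 labelled wild type (0.812) and without library 3 labelled knockout (0.870). Denervation and neuromuscular junction genes were higher for 8 and lower for 12 of 20 members (adjusted p = 0.522), and their median of -0.02 and mean of -0.01 went against camera's upward direction. Chrnb1, an acetylcholine receptor subunit gene, was at 45.6 ± 7.44 and 43.7 ± 9.56 FPKM, and Ache, acetylcholinesterase, at 32.7 ± 5.92 and 31.6 ± 3.87 FPKM. The direction of this list turned downward without library 1 labelled wild type (0.849). Regeneration and satellite cell genes were higher for 5 and lower for 9 of 14 members (adjusted p = 0.579), with desmin (Des) at 1607 ± 159 and 1531 ± 102 FPKM and cardiac actin (Actc1) at 161 ± 88.0 and 77.3 ± 20.2 FPKM. The regeneration list turned upward without library 3 labelled knockout (0.735). Cell cycle genes were higher for 2 and lower for 5 of 7 members (adjusted p = 0.0876), with Pcna at 29.0 ± 4.61 and 24.6 ± 0.986 FPKM and Mcm2 at 6.90 ± 1.70 and 6.18 ± 0.374 FPKM. Adjusted over the list alone 1 cell cycle gene passed, the spindle gene Tpx2, at 2.08 ± 0.148 and 1.15 ± 0.174 FPKM, named after its values were seen. The cell cycle list passed the preset-correlation test without library 2 labelled wild type (0.0344) and with no filter on low values (0.00334).

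Energy metabolism and ribosomal genes did not pass the test as lists. Oxidative phosphorylation genes were higher for 18 and lower for 39 of 57 members (median log2 difference -0.03, camera adjusted p = 0.648), with the ATP synthase genes Atp5b at 3444 ± 24.8 FPKM in libraries labelled wild type and 3633 ± 251 FPKM in those labelled knockout and Atp5a1 at 1601 ± 41.0 and 1680 ± 191 FPKM. Camera's direction for this list turned upward when each library's median was subtracted (0.795), under quantile normalization (0.532) and with library weights (0.272). With the preset correlation the list was called in opposite directions without library 1 labelled wild type (upward, 0.00458) and without library 2 labelled wild type (downward, 0.00390). With an estimated correlation 0 lists passed in either fit. Glycolysis genes were higher for 13 and lower for 9 of 22 members (adjusted p = 0.648), with a median of 0.01, a mean of -0.03, an upward direction in camera and a downward one in fry. Aldoa was at 14148 ± 666 and 14446 ± 1141 FPKM and Gapdh at 9184 ± 345 and 9441 ± 255 FPKM. Camera's direction for glycolysis turned downward without library 2 labelled wild type (0.551) and without library 1 labelled knockout (0.754). Fatty acid genes were higher for 8 and lower for 16 of 24 members (adjusted p = 0.390), with Fabp3 at 760 ± 186 and 553 ± 89.7 FPKM and Acadm at 552 ± 35.7 and 564 ± 46.4 FPKM, and the list passed without library 3 labelled wild type (0.000154). It turned upward without library 1 labelled wild type (0.460) or library 2 labelled knockout (0.938). Ribosomal protein genes were higher for 26 and lower for 49 of 75 members (adjusted p = 0.390), with Rplp0 at 992 ± 52.8 and 910 ± 46.2 FPKM and Rps2 at 839 ± 35.2 and 758 ± 7.86 FPKM. With the preset correlation, the ribosomal list was called downward without library 2 labelled wild type (0.00390), library 2 labelled knockout (0.0292) or library 3 labelled knockout (0.00515). It was called upward without library 1 labelled knockout (0.0298). The ribosomal list also turned upward, without passing, without library 1 labelled wild type (0.0734) and with library weights (0.0631). With an estimated correlation 0 lists passed in any of these fits, or in that without library 3 labelled wild type.

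Circadian clock genes were higher for 14 and lower for 5 of 19 members in the libraries labelled knockout (median log2 difference 0.04), and the list passed camera with the preset correlation (adjusted p = 0.0106). It missed it with an estimated correlation (adjusted p = 0.433), and its call was lost without library 2 labelled wild type (0.0563) or library 2 labelled knockout (0.118). Tef, a transcription factor of clock output, was at 201 ± 9.75 FPKM in libraries labelled wild type and 224 ± 11.6 FPKM in those labelled knockout, and the glucocorticoid-inducible Tsc22d3 at 153 ± 31.9 and 164 ± 65.8 FPKM. Immediate-early genes were higher for 5 and lower for 17 of 22 members (adjusted p = 0.168), with Nr4a1 at 73.9 ± 16.5 and 87.8 ± 38.1 FPKM and Dusp1 at 72.4 ± 13.8 and 66.5 ± 33.6 FPKM. That list passed camera with the preset correlation when each library's median was subtracted (0.0353), and without library 1 (0.0183) or 2 (0.00813) labelled knockout. Its score was lowest in library 3 labelled knockout (-0.50), and without that library its direction turned upward (0.106).

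The remaining cell type lists and the genes around the targeted locus did not pass. Endothelial markers were lower for 14 of 17 members (camera adjusted p = 0.390), with Aqp1 at 205 ± 12.5 FPKM in libraries labelled wild type and 218 ± 20.9 FPKM in those labelled knockout and Ly6c1 at 137 ± 27.3 and 127 ± 11.1 FPKM. Smooth muscle and pericyte markers were lower for 8 of 12 members (adjusted p = 0.593), with Des as above and Rgs5 at 173 ± 46.5 and 170 ± 14.9 FPKM. Both lists passed camera with the preset correlation without library 1 labelled wild type (0.00836 and 0.000825) and with library weights (0.0360 and 0.0383). With an estimated correlation 0 lists passed under either setting. The smooth muscle list turned upward without library 2 (0.551) or 3 (0.641) labelled wild type or library 3 labelled knockout (0.962). Schwann cell markers were higher for 5 of 8 members (adjusted p = 0.583), with Pmp22 at 33.0 ± 3.49 and 29.9 ± 3.88 FPKM, and the list turned downward with library weights (0.988). Erythrocyte markers were lower for 6 of 7 members (adjusted p = 0.337), with Hbb-bs at 286 ± 95.8 and 291 ± 76.7 FPKM and Hba-a1 at 183 ± 50.5 and 169 ± 43.2 FPKM. The erythrocyte list passed camera with the preset correlation without library 2 labelled wild type (2.4e-05), where 0 lists passed with an estimated correlation. It turned upward without library 3 labelled wild type (0.812) or library 1 labelled knockout (0.754). Genes flanking the Mettl21e locus were higher for 11 and lower for 11 of 22 members (adjusted p = 0.648), with a median of -0.01 and a mean of -0.05 against an upward direction in camera. Among them, Col3a1 was at 77.9 ± 34.5 and 50.7 ± 10.4 FPKM and Hibch at 39.8 ± 2.104 and 41.4 ± 2.81 FPKM. The flanking list turned downward without library 2 (0.850) or 3 (0.947) labelled wild type and without library 2 (0.957) or 3 (0.962) labelled knockout. In 23 of the 28 tested lists 0 members passed even adjusted over the list alone, and the list of sex-linked genes had too few members above the filter to be tested. Over the 28 lists 10 passed camera with the preset correlation, 8 lower and 2 higher, and 0 passed with an estimated correlation or with fry. Without library 1 labelled knockout 2 lists passed fry.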

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

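limma voom was chosen after seeing the data, and all other alternatives beforehand. The count of genes called was 0 under every setting with all 6 libraries, and 0 to 3 on leaving out 1 library, with 0 to 1 higher, 0 to 2 lower and 0 to 3 changed at least 2-fold. Genes at an unadjusted p under 0.05 numbered 523, against 987 with no filter, 339 with a mean of at least 5 FPKM, 1413 with library weights and 341 to 1357 on leaving out 1 library. Subtracting medians moved the median log2 difference from -0.024 to 0.023. The lists past camera numbered 10, but 0 with an estimated correlation, 0 with fry and 6 with a mean of at least 5 FPKM, where fewer genes were tested, and 7 to 14 on leaving out 1 library. With an estimated correlation 0 lists passed under every setting, while fry passed 1 list with library weights and 2 without library 1 labelled knockout. Depth limits genes as low as Mettl21e, where 8 to 63 fragments stand behind a library. Apart from smaller sets of genes or libraries, the cause of the changes below was not tested. The alternatives written for raw counts were not run, because the unit is FPKM, and the sex-linked list could be tested only with no filter (adjusted p = 0.493).

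With an estimated correlation the adjusted p of the 10 lists was 0.508 for slow fibre genes, 0.757 for fast fibre genes, 0.433 for heat shock and clock genes, and 0.715 for the antigen presentation, interferon, fibroblast, tendon, leukocyte and adipocyte lists. With fry it was 0.459 for slow fibre, 0.850 for fast fibre and 0.123 for heat shock genes, 0.627 for the clock, interferon and adipocyte lists, 0.652 for the antigen presentation and leukocyte lists and 0.692 for the fibroblast and tendon lists, and fry reversed the direction of glycolysis and flanking genes (0.953 for both). A mean of at least 5 FPKM ended the call of fast fibre (0.0536), interferon (0.149) and adipocyte genes (0.317), voom that of adipocyte markers (0.0535), and quantile normalization (0.174) and no trend (0.0568) that of fast fibre genes. Cell cycle genes passed with no filter (0.00334), immediate-early genes with medians subtracted (0.0353), and endothelial (0.0360) and smooth muscle markers (0.0383) with library weights. Library weights reversed the proteasome (0.715), ribosomal (0.0631), Schwann cell (0.988) and oxidative phosphorylation (0.272) lists, the last also reversed with medians subtracted (0.795) and by quantile normalization (0.532).

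With the replicate number as a block (the replicate block fit), 0 genes were called, fast fibre genes missed the test (adjusted p = 0.0556) and immediate-early genes passed it (0.0279). The numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.024, -0.041 and 0.023, and the pairs made of 1 library of each label lay between -0.052 and 0.032.

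On leaving out 1 library, the adjusted p of lists that changed call or direction was: METTL21 family and substrates 0.196 to 0.795, 26S proteasome 0.0606 to 0.754, immunoproteasome and antigen presentation 1.1e-06 to 0.0800, atrophy genes 0.0298 to 0.957, fast-glycolytic fibre genes 4.6e-04 to 0.373, oxidative phosphorylation 0.00390 to 0.985, glycolysis 0.223 to 0.802, fatty acid use 1.5e-04 to 0.938, cytosolic ribosomal proteins 0.00390 to 0.0968, growth signalling and hypertrophy 0.460 to 0.870, denervation and neuromuscular junction 0.0629 to 0.951. For the other such lists it was: regeneration and satellite cells 0.157 to 0.890, cell cycle 0.0344 to 0.291, circadian clock 0.00221 to 0.118, immediate-early genes 0.00813 to 0.396, interferon response 1.2e-04 to 0.235, tendon markers 1.6e-04 to 0.519, endothelial markers 0.00836 to 0.994, smooth muscle and pericyte markers 8.3e-04 to 0.962, adipocyte markers 0.00390 to 0.291, erythrocyte markers 2.4e-05 to 0.812 and flanking genes of the Mettl21e locus 0.272 to 0.962.

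The log2 difference of Mettl21e ranged from -0.068 to 0.63 on leaving out 1 library. Of 96 other named genes, 69 had the same direction under all settings and 27 reversed under at least 1. With medians subtracted, Psmc3 (0.026), Ubb (0.0086) and Ache (0.0076) reversed; with quantile normalization, Psmc3 (0.013) and Mybpc1 (-0.025); with voom, Mybpc1 (-2.9e-05). Library weights reversed Mybpc1 (-0.015), Aspscr1 (-0.0060), Rgs5 (-0.095), Mettl18 (0.058), Mettl21c (0.0038) and Vcpkmt (-0.0031). On leaving out 1 library, the log2 differences that changed sign ranged as follows: Mcm2 -0.24 to 0.050, Irf1 -0.081 to 0.15, Ubb -0.071 to 0.016, Mybpc1 -0.10 to 0.14, Nr4a1 -0.11 to 0.57, Ache -0.19 to 0.043, Dusp1 -0.60 to 0.18, Aspscr1 -0.059 to 0.10, Atp5a1 -0.025 to 0.13, Mettl21a -0.12 to 0.088, Des -0.11 to 0.012, Rgs5 -0.24 to 0.15, Trim63 -0.041 to 0.22, Aldoa -0.017 to 0.094, Tsc22d3 -0.24 to 0.39, Nedd4 -0.0085 to 0.068, Nploc4 -0.050 to 0.10, Chrnb1 -0.23 to 0.060, Mettl18 -0.41 to 0.11, Mettl21c -0.25 to 0.0073, Hbb-bs -0.26 to 0.28, Acadm -0.031 to 0.086, Hba-a1 -0.35 to 0.12, Ly6c1 -0.18 to 0.064 and Mettl23 -0.056 to 0.14.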

Other observations

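The tests of swapped labels, of uneven sampling of slow fibres, of residual blood and of glucocorticoid-responsive genes were chosen only after the results they bear on were seen.

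Library 3 labelled wild type held neutrophil granule transcripts that were far lower in the other 5 libraries. S100a8 and S100a9, which encode the calprotectin subunits, were at 70.8 and 67.1 FPKM there and at most at 6.95 and 7.09 FPKM elsewhere. Ltf, the lactoferrin gene, was at 36.7 FPKM against at most 0.271 FPKM, and Ngp at 30.7 FPKM against at most 0.483 FPKM. Of genes above 5 FPKM in a library, counted with 0.5 FPKM added to all values, 13 were more than 3 times above every other library there, against 15 in library 2 labelled wild type, 1 each in library 1 of either label and 0 in libraries 2 and 3 labelled knockout. These genes were picked after their values were seen.

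In library 2 labelled wild type, the ribosome biogenesis gene Rrp1 was at 33.3 FPKM against at most 2.70 FPKM elsewhere, Rpl12 at 193.9 against at most 14.5 FPKM, mt-Nd4l at 54.3 against at most 2.19 FPKM and Gm26917 at 58.7 against at most 2.90 FPKM, all picked after their values were seen. Gm26917 and Gm42418, counted here as ribosomal RNA loci, together held 0.0191% of its fragments, against 0.00057% to 0.00096% in the other libraries. The cause of these differences was not tested.

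Mettl21e fragments were present in every library labelled knockout. Fragments shared with a near-identical gene are argued against by the sequence, since 0.2285% of the 3938 50-base words of its transcripts occur in transcripts of other genes. A swap of the labels between the groups stays open: the lowest library labelled wild type held 8 fragments, but an allele that leaves a transcript would give fragments under either labelling. Such an allele, fragments of the overlapping Gm15833 and single wrong labels are open and untested too, because there is 1 value per gene. Whether Mettl21e may follow glucocorticoid-responsive genes cannot be told apart from no relation over 6 libraries: Spearman's rho with the mean of 12 such genes was 0.2 (exact permutation p = 0.714) and Pearson's r was 0.547 (exact permutation p = 0.279). Without the 2 libraries farthest from the median r was 0.620, and the upper bound of rho was 0.870 by Fisher's z.

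Slow and oxidative fibre genes stood lower in the libraries labelled knockout in camera with the preset correlation, while the list missed camera with an estimated correlation (adjusted p = 0.508) and fry (0.459). With the fibroblast list mean as a covariate, the median log2 difference of the list was -0.44, against -0.49 without it. The fibroblast mean thus accounted for little of its size. The list kept an adjusted p of 2.2e-07 in camera with the preset correlation. That p cannot decide against a general loss of non-muscle tissue, because the same test also passed this list in splits that mixed the labels. The covariate fit was not repeated with an estimated correlation or fry. Uneven sampling of a slow-fibre part of the muscle may contribute: for 2 of the 4 type I genes Myh7, Tnnt1, Tnnc1 and Tnni1, library 3 labelled wild type lay inside the range of the libraries labelled knockout. It lay below that range for Tnnc1 and above it for Myh7. The median ratios of the 4 genes to the knockout-labelled mean were 4.47, 5.60 and 0.8003 in libraries 1, 2 and 3 labelled wild type. For Csrp3, Ankrd2 and Myh2, however, library 1 and not library 3 lay inside the range of the libraries labelled knockout. The low library was thus not the same for all slow-list genes. With 3 libraries per label uneven sampling cannot be told apart from an effect of genotype, which stays open.

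The same covariate changed other calls of camera with the preset correlation. The calls of the antigen presentation (adjusted p = 0.130), interferon (0.101), leukocyte (0.332), tendon (0.930), adipocyte (0.625), fast fibre (0.826) and clock (0.0541) lists were lost, and that of the fibroblast list itself (0.826), whose mean was the covariate. The median log2 difference of the clock list rose from 0.04 to 0.12 with the covariate, so its lost call does not reflect a smaller difference. The medians of the other lists that lost their call shrank in size. The proteasome (0.00859), oxidative phosphorylation (2.0e-05), ribosomal (4.3e-04) and fatty acid (0.00859) lists passed as lower in the libraries labelled knockout, and the smooth muscle list (0.0481) as higher. In the order given, the medians of the lower lists with the covariate were -0.08, -0.09, -0.08 and -0.12. These calls rest on the preset correlation alone, since the covariate fit was not repeated with an estimated correlation or fry. The heat shock list kept its call (6.1e-07).

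For the myeloid transcripts of library 3 labelled wild type, bone marrow cells are a candidate source. Over 28 marrow precursor genes listed without looking at their values, 27 were above 0 in some library and this library was the highest for 24, or 88.9%, with a median ratio of 10.1 to the mean of the others. The most abundant were Pf4, at 9.74 FPKM against 3.39 to 6.51 FPKM, and Retnlg, at 4.28 FPKM against at most 0.303 FPKM. The mean of the other libraries reached 1 FPKM for 2 of the listed genes, and 1 is in another list. Over 4 haemoglobin genes the median ratio to the other libraries was 1.34. For the myeloid transcripts this argues against more blood left in the tissue. The erythrocyte gene Slc4a1, picked after its values were seen, was raised here, with a ratio of 32.25 to the mean of the others. The erythrocyte list scored 0.73 here, against -0.48 to 0.13 in the other libraries, but the list holds Slc4a1, so its score is not separate evidence. The source of these erythrocyte transcripts stays open. Whether marrow cells would leave haemoglobin this little raised was not tested, and no biological explanation was tested.

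The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes and the highest of the others 1, and with a real count of 0 all 10 splits give at least as many by construction, so this count says nothing about chance. For lists passing camera with the preset correlation, the real split gave 10 and the highest of the others 12, and 4 of the 10 splits gave at least 10. The slow and oxidative list passed in 6 of the 10 splits, and its adjusted p was 1.7e-12 for the split that set libraries 1 and 2 labelled wild type with library 2 labelled knockout, below the 2.8e-08 of the real split. The call of this list is therefore not particular to the labels. Every other split keeps most libraries of a label together, so a difference between the labels could also pass there. The splits thus cannot decide against such a difference. The split that set library 1 labelled wild type with libraries 2 and 3 labelled knockout gave 1501 genes at an unadjusted p under 0.05, against 523 for the real split, which points to a structure of the samples.

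Flanking DNA of a donor strain would raise the share of differing genes near the locus. Within 10 Mb of Mettl21e, 1 of 77 tested genes (1.30%) had an unadjusted p under 0.05, against 4.62% elsewhere (Fisher's exact test, two-sided, p = 0.267), which argues against a raised share there between these labels. With 77 genes a small rise could have been missed. Wrong labels of single libraries, which stay open, could also hide one.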
